A study of Homo sapiens with 6 samples.

How the data were processed

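Total RNA from 6 cultures of human aortic vascular smooth muscle cells (3 donors, each with an untreated and an IL-17-treated culture at passage 3, in medium with 20% fetal calf serum) was turned into biotin-labelled target and hybridised to short oligonucleotide arrays with 54675 probe sets, per the labels. Groups and donors were taken from the sample titles. The submitters' design text states that each donor gave both cultures.

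The deposited table holds an intensity per probe set and array on a linear scale. The submitters' processing notes name RMA, with no version and no role. RMA gives quantile-normalized log2 values, and the deposited values are neither: they reach from 0.079 to 57610, the arrays' quartiles differ, and every array has the same trimmed mean (500.07 to 500.08 after trimming 2% at each end). How the authors made these intensities, including the background correction and the summary over probes, is not given in the sources used here. Scaling to a common trimmed mean leaves differences in the shape of the arrays' distributions in place. Between 17 and 147 probe sets per array had intensities under 1, where a log2 difference is large but carries little information, and for this reason dim probe sets were filtered. Detection calls were not used here. The test had been planned for log2 values, with log2 to be taken if the values were linear, and this was done with no offset and no further normalization between arrays.

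Probe sets were named through the platform annotation supplied with the values. Of 54613 non-control probe sets, 41091 had 1 gene symbol, 1801 had several and were not used, and 11721 were unnamed here. Of the probe sets with 1 symbol, 41037 had a gene identifier in the RefSeq gene table, and 0 symbols changed through it. The 62 control probe sets were left out. Genes of the Y chromosome and XIST were left out of all tables, since the donors are people. Each of the 19740 genes was represented by its probe set with the highest mean over the 6 arrays. A gene was tested if this probe set lay above the array's median on at least 3 of the 6 arrays, whichever their group, which left 12367 genes. No genome build is named for these values and no coordinates are given.

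Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided) with the donor as a block, and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. The fit had 2 residual degrees of freedom and a prior of 2.36. Whether the donor letters pair the arrays was checked on the deviations from the group means: the correlation across genes between the untreated and the IL-17 array was 0.44, 0.50 and 0.55 for arrays of the same donor and between −0.37 and −0.12 for arrays of different donors. An exact sign-flip test on 3 pairs cannot give a two-sided p under 0.25, so none is reported per gene.

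There were 29 gene lists, written before the data were examined from general knowledge of IL-17 signalling, NF-kB, vascular biology and the other cell types that such cultures could hold. The 28 lists with at least 5 tested members were tested with limma's camera (inter-gene correlation 0.01, two-sided) in the same model, and p-values were adjusted over the lists. Beside each call stands camera's p with the correlation estimated from the residuals. Limma's fry was run as an alternative. Members were also adjusted over their list alone. Of the 30 IL-17 response genes written, 25 were on the array under a single symbol and 17 were tested. The dimmer members among the 25 were tested only with the filter on dim probe sets left out. Those with no probe set under a single symbol were not analysed. The lists overlap, for example in CCL20 and NFKBIZ.

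The rule for named genes, also set before the data were examined, took the genes with the largest differences past the threshold in all donors (none passed), up to 4 members with the smallest p of each list called by camera, 14 genes fixed in advance where measured (the IL-17 receptor and its adaptor, the main cytokines and chemokines, NFKBIZ, NFKBIA and contractile markers) and, since fewer than 10 genes passed, the 10 genes with the smallest p.

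The analysis was tested on simulated data, in 20 simulations of the 12367 genes with the donors' real levels, variances drawn from the prior that limma estimated and 200 genes changed. The comparison recovered 1% of genes changed by 1 on the log2 scale, 61.5% of those changed by 2, 84.3% by 3 and 91.7% by 4, with 6 false among 125 calls on average. Each changed gene had the same effect in every donor. In the real arrays some responders differed widely between donors, such as CXCL8 with an SD of 1.57, against a median SD of 0.324 over all genes. The recovery rates do not give the power for such genes. A shift of 0.5 of the IL-17 response list, with independent genes, was called in 100% of simulations by camera with the correlation of 0.01 and in 0% with an estimated correlation. With no shift, 0% of simulations called any list. Since the simulated genes were independent, this does not measure false calls among correlated genes. In the real arrays the correlation estimated for the IL-17 response list was 0.55.

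The alternatives were no donor block, a prior with an intensity trend and robust estimation, no filter and a stricter filter on dim probe sets, the mean of a gene's probe sets, quantile, median and cyclic loess normalization, leaving out each donor, other thresholds, the estimated correlation and fry. In camera, that prior had the intensity trend alone, without robust estimation. The log2 of the intensity plus 50 was added after the data had been seen. The adjustment over each list alone was planned, and repeating its count for the IL-17 response genes under the alternatives was chosen after the data had been seen. Figures and summaries were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.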

Results

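Gene expression was measured with oligonucleotide arrays in vascular smooth muscle cells grown from the aortas of 3 donors, called A, B and C. From each donor, a culture at passage 3 was left untreated and another was exposed to interleukin 17 (IL-17), an inflammatory cytokine made mainly by T cells, at 100 ng/ml for 6 h. The labels do not say whether the untreated cultures had a vehicle or a change of medium at the same time, so each difference below is that of IL-17 together with anything else that was done to the treated cultures alone. This gave 3 untreated and 3 IL-17 arrays, which is the number that limits the precision of every value below. The median intensity per array ranged from 74.3 to 101 on a scale where every array's 2% trimmed mean was about 500. The 3'/5' ratio of the GAPDH control probe sets, a measure of RNA integrity, lay between 0.862 and 0.957 on the 6 arrays, and that of ACTB between 1.09 and 1.31. The design implies a single comparison, which asks how IL-17 changes gene expression in these cells, with each treated culture set against the untreated culture of its own donor. Values are given as the mean log2 difference (IL-17 minus untreated) ± SD of the 3 donor differences, n = 3.

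Among the 17 tested genes of a list of known IL-17 response genes, CCL20, NFKBIZ and IL6 rose after IL-17 when p-values were adjusted over the list alone. CCL20, a chemokine that attracts cells bearing CCR6, rose by 2.42 ± 0.74 (5.35-fold), from a geometric mean intensity of 309 to 1655. NFKBIZ, which encodes the nuclear NF-kB cofactor IkB-zeta, rose by 1.18 ± 0.27 (2.27-fold), and its other probe set gave 1.25 ± 0.18. IL6, a pleiotropic inflammatory cytokine, rose by 1.10 ± 0.37 (2.14-fold) from an already bright 10740 to 23000. All 3 genes were higher in each of the 3 donors, with adjusted p = 0.0164, 0.0164 and 0.0252 over the list alone (limma). None of them passed when adjusted over all 12367 genes tested (adjusted p = 0.581 for each). With a donor left out, the differences of CCL20, NFKBIZ and IL6 stayed close to these values, at 2.34, 1.18 and 1.16 without B and 2.10, 1.05 and 0.89 without C, but 0 list members then passed adjusted over the list alone (adjusted p = 0.0912 and 0.0813 for each of the 3 genes), against 10 members without donor A. The count was also 0 without the donor block and with no filter on dim probe sets. Quantile normalization ended the call on IL6 alone.

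The IL-17 response list as a whole was higher after IL-17 relative to the other genes (camera, adjusted p = 1.9e-05), with a median log2 difference of 0.84 over its 17 members. With an estimated correlation between its genes the call was lost (adjusted p = 0.711), as it was with fry (adjusted p = 0.552). Without donor B the median was 0.46. In the simulations, however, that form of camera called 0% of true shifts of 0.5 of this list. A call lost in this way, here and for the lists below, therefore cannot tell a false call from a true one. The chemokines of the list differed widely between donors. CXCL8, the neutrophil chemoattractant interleukin 8, had a difference of 1.88 ± 1.57 with donor values of 0.56 in A, 3.62 in B and 1.47 in C, and CXCL1, of the same family, had 1.58 ± 1.79 with −0.41, 3.04 and 2.11. CCL2, which attracts monocytes, had 0.66 ± 0.61, with −0.04 in donor A and about 1 in both other donors (1.06 and 0.95). Without donor A these 3 means were 2.54, 2.58 and 1.01, and without donor B 1.01, 0.85 and 0.45. Of the NF-kB inhibitors of the list, TNFAIP3 had 0.55 ± 0.22. NFKBIA had −0.19 ± 0.85, with −1.18 in donor A, 0.32 in B and 0.28 in C. Its mean turned to 0.30 without donor A and to 0.23 when all its probe sets were averaged, and was −0.45 without donor B and −0.43 without C. CXCL3 (1.85 ± 1.75) and PTGS2, the inducible cyclooxygenase (1.48 ± 1.96), lie outside the rule for named genes and were chosen after their values were seen. They too were largest in donor B, with 0.44 in A, 3.81 in B and 1.29 in C for CXCL3 and −0.49, 3.43 and 1.51 for PTGS2. Adjusted over the list alone, these 7 genes had p-values from 0.112 to 0.664. Altogether 8 of the 17 members were higher in all 3 donors and 0 were lower in all 3. The list's median per donor was −0.04 in A, 1.19 in B and 1.11 in C. CSF3, the granulocyte growth factor, was too dim to be tested, with a geometric mean intensity of 13.3 untreated and 69.0 after IL-17. It was higher in all 3 donors, with log2 differences of 0.50 in A, 2.43 in B and 4.19 in C. Of the other members too dim to be tested, LCN2 went from 48.3 to 15.9 and was lower in all 3 donors. Its differences were −2.9 in A, −1.79 in B and −0.12 in C. IL19 and MMP3 also had lower means after IL-17, and S100A8, S100A9, IL36G and MMP13 had higher ones. Of these, only S100A9 went the same way in all 3 donors, with 2.15 in A, 2.48 in B and 1.02 in C.

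**Figure D1:**
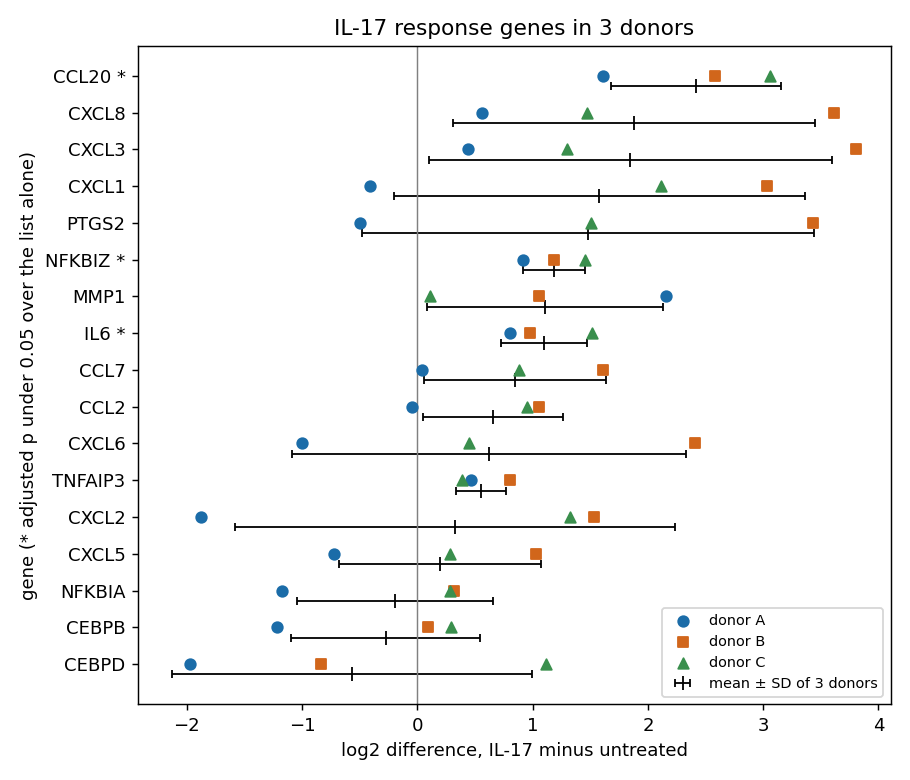
Log2 difference (IL-17 minus untreated, horizontal axis) of the 17 tested IL-17 response genes (vertical axis), with a coloured symbol per donor and a black mark with bars for the mean ± SD of the 3 donors. The 3 starred genes, CCL20, NFKBIZ and IL6, passed when adjusted over the list alone, and donor A lies to the left of donors B and C for the chemokines plotted, such as CXCL1 at −0.41 against 3.04 and 2.11.

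A pair of further lists was also higher by camera. The immediate early and AP-1 genes, transcription factors and phosphatases induced quickly by many stimuli, had a median difference of 0.38 over 23 tested members (adjusted p = 0.00583, and adjusted p = 0.711 with an estimated correlation). Of these, 10 were higher in all 3 donors and 1 was lower in all 3, and 0 passed either over all genes or adjusted over the list alone, where the smallest adjusted p was 0.0924. The members with the smallest p were MAFF, a small MAF transcription factor (1.22 ± 0.52), DUSP1, a MAP kinase phosphatase (0.66 ± 0.20, and 0.37 with averaged probe sets), IER3 (0.65 ± 0.20) and the nuclear receptor NR4A3, whose 2.74 ± 1.85 came from 3.35 in donor A, 4.20 in B and 0.67 in C. NR4A3 was dim, at 63.1 in untreated cells. Its other probe sets gave 3.16 ± 0.98 and −0.24 ± 0.03, and the averaged probe sets 1.89. The NF-kB subunits and feedback inhibitors had a smaller median of 0.11 over 23 members (adjusted p = 0.0204, and adjusted p = 0.711 with an estimated correlation). NFKBIZ passed adjusted over that list alone (adjusted p = 0.0444), while TNFAIP3 did not, nor did NFKBID (0.79 ± 0.16) and NFKBIB (1.18 ± 0.57, and 0.70 with averaged probe sets), both on dim probe sets. The median of the NF-kB list was 0.38 without donor A, and its call was lost without donor B (median 0.06, adjusted p = 0.199), without donor C (median 0.04, adjusted p = 0.274) and with no filter on dim probe sets (adjusted p = 0.127). The immediate early list had a median of 0.63 without donor C and lost its call without donor B (median 0.15, adjusted p = 0.0722). With fry, both lists lost their call (adjusted p = 0.552 for the immediate early list and 0.568 for the NF-kB list).

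The list of chemokines had a median of 0.26 over 16 tested members and was not called (camera adjusted p = 0.143). Its median was 0.83 without donor A, where the list was called (adjusted p = 0.000135), 0.17 without C and −0.03 without B. The list was also called with the trended prior (adjusted p = 0.042) and the stricter filter on dim probe sets (adjusted p = 0.0111). A single member, CCL20, passed adjusted over this list alone (adjusted p = 0.019). Cytokines and haematopoietic growth factors had a median of 0.35 over 16 members (adjusted p = 0.134), with 0 past the threshold adjusted over the list alone. Of these members, 7 were higher and 3 lower in all 3 donors. Their median was 0.19 without donor B and 0.13 with averaged probe sets, and the list was called with that prior (adjusted p = 0.0358) and with that filter, where the median was 0.99 (adjusted p = 0.000252). The differences of the receptor subunits that bind IL-17 were smaller than the spread between donors. IL17RA, at 593 in untreated cells, had 0.42 ± 0.50, and IL17RC, at 640, had −0.12 ± 0.32, a sign shared by 1 of its 3 other probe sets and turned to 0.01 without donor A. IL17RA ranged from 0.18 without donor B to 0.67 without donor C, and IL17RC was −0.30 without donor B. TRAF3IP2, the adaptor Act1 that couples the receptor to NF-kB, had −0.13 ± 0.21 (−0.24 without donor C to −0.03 without donor A). Their list, the receptor and its proximal signalling, had a median of 0.01 over 23 members, between −0.07 and 0.06 under the alternatives (adjusted p = 0.724).

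The contractile genes that mark differentiated smooth muscle had a median difference of 0.08 over 27 tested members (camera adjusted p = 0.683). This median turned to −0.12 without donor A and to −0.02 with averaged probe sets, and was 0.15 without donor B. Of the members, 4 were higher in all 3 donors, 4 were lower in all 3 and 0 passed the threshold over all genes or over the list alone. Smooth muscle actin, ACTA2, was bright (18360 untreated and 20820 after IL-17) and had a difference of 0.18 ± 0.36. This difference turned to −0.72 when its dim probe sets were averaged in and to −0.01 without donor A, and was 0.34 without donor B. The actin-binding protein TAGLN had 0.21 ± 0.34, with 0.02 without donor A and 0.34 without donor C. The myosin heavy chain MYH11 was too dim to be tested, at 22.1 untreated and 49.4 after IL-17.

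Of the other lists tested with camera, 0 were called in either direction, and many of their medians moved with the setting or the donors used. The range over all alternatives, leaving out a donor included, stands in brackets after each median. The median difference was 0.02 for the mRNA decay regulators of cytokine messages (−0.06 to 0.08), −0.20 for complement and acute phase proteins (−0.42 to 0.09), 0.02 for matrix metalloproteinases, ADAMTS and inhibitors (−0.06 to 0.08), −0.14 for leukocyte adhesion molecules (−0.25 to −0.03) and 0.22 for prostaglandin and nitric oxide synthesis (0.10 to 0.37). It was −0.18 for the type I interferon-stimulated genes (−0.31 to −0.08), −0.08 for the interferon-gamma response and antigen presentation (−0.17 to −0.02), −0.27 for STAT3 feedback and IL-6 family signalling (−0.47 to −0.003), −0.03 for extracellular matrix proteins (−0.08 to 0.02) and 0.10 for TGF-beta targets (0.02 to 0.15). Cell cycle genes had a median of 0.16 (−0.07 to 0.25), the oxidative stress and metal response 0.14 (0.08 to 0.19), endoplasmic reticulum stress genes 0.06 (−0.01 to 0.10) and hypoxia and glycolysis genes −0.002 (−0.04 to 0.05). Apoptosis regulators had 0.09 (0.06 to 0.14) and osteogenic and calcification genes 0.37 (0.13 without donor A to 0.67 without donor C). The genes of sterol synthesis and uptake had a median of 0.23 (0.09 to 0.28) and came closest to a call (adjusted p = 0.0525). The adjusted p of these other lists, sterol synthesis included, ranged from 0.0525 to 0.993. With a donor left out, some were called: prostaglandin and nitric oxide synthesis higher without A (adjusted p = 0.0191), endoplasmic reticulum stress genes higher without B (adjusted p = 0.0432), and without C sterol synthesis higher (adjusted p = 0.0142) and STAT3 feedback lower (adjusted p = 0.0362). The trended prior called sterol synthesis and oxidative stress higher and STAT3 feedback lower (adjusted p = 0.0358 for each). The stricter filter called oxidative stress higher (adjusted p = 0.0381) and log2 of the intensity plus 50 sterol synthesis higher (adjusted p = 0.0488). The test's direction differed in sign from the median for the receptor, extracellular matrix and hypoxia lists, and from the mean for the mRNA decay, extracellular matrix and endothelial lists.

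Markers of other cell types were also not called as lists. Their median difference, with the range over the alternatives in brackets, was −0.17 for endothelial cells (−0.39 to 0.15), −0.19 for adventitial fibroblasts (−0.29 to −0.005), −0.30 for pericytes (−0.33 to 0.25, the latter without donor B) and −0.33 for T, B and NK cells (−0.55 to −0.14), of which 5 markers were bright enough to be tested. CD3E, a subunit of the T cell receptor complex, had −1.09 ± 0.51 at a dim 113.5 untreated and 53.5 after IL-17, and passed adjusted over that list alone (adjusted p = 0.0486) but not over all genes. That call was lost without the donor block (adjusted p = 0.468), without donor B (0.152) or C (0.193), with no filter (0.231), with the trended robust prior (0.387) and with quantile (0.155), median (0.0685) and cyclic loess (0.102) normalization. Apart from CCL20, NFKBIZ, IL6 and CD3E, 0 members of any list passed adjusted over their list alone. Monocyte and macrophage markers had a median of −0.34, but with 4 tested members they were too few for the list test.

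**Figure D2:**
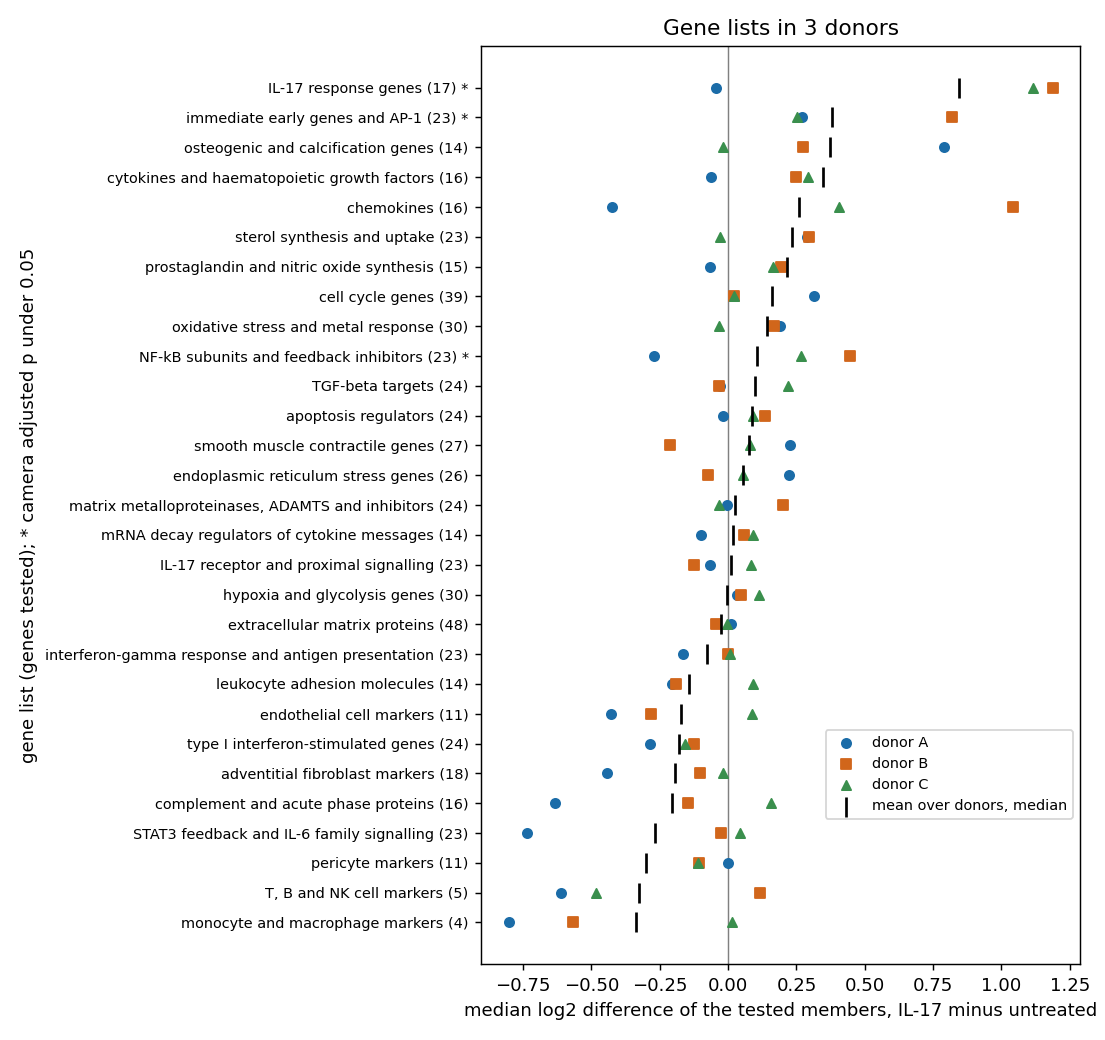
Median log2 difference (IL-17 minus untreated, horizontal axis) of the tested members of each gene list (vertical axis, with the number of genes tested), with a coloured symbol per donor and a black bar for the median of the 3-donor mean differences. The 3 starred lists had a camera adjusted p under 0.05; the IL-17 response genes had donor medians of −0.04 in A, 1.19 in B and 1.11 in C.

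Across the whole array, 0 genes were higher and 0 lower at an adjusted p under 0.05 (limma with the donor as a block, smallest adjusted p = 0.581). At an unadjusted p under 0.05 there were 388 higher and 574 lower genes, together 962 against 618 expected by chance. This count was 460 without donor A and 494 without B, both under 618, and 1380 without C. Without the block, 369 genes had an unadjusted p under 0.05 and 0 passed after adjustment. The 10 genes with the smallest p, which did not pass, were mostly dim. Besides CCL20, the positive differences were those of PTPRE (1.58 ± 0.22), RELT of the TNF receptor family (1.79 ± 0.37), DOHH (1.19 ± 0.21) and the non-coding RNAs CACNA1G-AS1 (2.07 ± 0.58) and LINC00482 (1.48 ± 0.35). The negative ones were those of LAIR2, a secreted collagen-binding receptor (−2.20 ± 0.16), ULBP1, a ligand of the NKG2D receptor (−1.35 ± 0.29), RASL11B (−1.30 ± 0.28) and MAML3 (−1.29 ± 0.26), for which both other probe sets went the opposite way, and 1 of the 2 other probe sets of PTPRE did so too. These opposing probe sets were very dim, at 19.3 and 17.2 for MAML3 and 10.2 for PTPRE. Each lay below the lower quartile of every array (21.9 to 28.9). The geometric mean intensity of the 10 genes in untreated cells, CCL20 aside, lay between 25.9 for CACNA1G-AS1 and 206.6 for MAML3, so that the size of their differences depends on the log scale. On log2 of the intensity plus 50, LAIR2 had −1.16, ULBP1 −0.73, RASL11B −0.83, RELT 1.18, CACNA1G-AS1 1.01 and LINC00482 0.85, while CCL20 had 2.21.

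The 3 donors differed in how much changed. Over the 7478 brightest genes (mean above the 75th percentile of the arrays), the SD of the log2 differences was 0.598 in donor A, 0.506 in B and 0.217 in C, and 573, 339 and 22 genes differed by over 2-fold. Pearson's r of the differences across these genes was 0.436 between donors A and B, 0.153 between A and C and 0.228 between B and C; genes are not independent replicates, so no p-value is attached. Of all 12367 genes, 2008 were higher and 2412 lower in all 3 donors, 35.7% together where independent donors with even odds would give 25%.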

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

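The log2 of the intensity plus 50, and repeating the count of IL-17 response genes adjusted over the list alone under the alternatives, were chosen after the data had been seen. The counts of genes higher and lower over all genes were 0 under every alternative, the looser thresholds included, with 369 to 1380 genes at an unadjusted p under 0.05. The number of lists called higher by camera, 3 in the report, was 7 with the trended prior and 6 with the stricter filter on dim probe sets. It was 0 with the estimated correlation and 0 with fry (adjusted p = 0.711 and 0.552 for the IL-17 response list), and between 2 and 5 when a donor was left out. The estimated correlation also called 0% of the simulated shifts of 0.5 of the IL-17 response list, with independent genes. Its loss of that list therefore cannot tell a false call from a true one at such a shift. No shift of the other lists was simulated, and fry was not run on the simulations. The number of lists called lower, 0 in the report, was 1 with the trended prior and from 0 to 1 when a donor was left out. The list was STAT3 feedback and IL-6 family signalling, without donor C and with that prior. The camera call on the IL-17 response list held under the other alternatives, with adjusted p from 1.36e-15 without donor A to 0.011 without donor C.

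Without the donor block, 0 IL-17 response genes passed adjusted over the list alone, against 3 with it, and the same 3 lists were called (adjusted p = 0.000576 for the IL-17 response genes). The block changed no call over all genes. That count was 0 with no filter on dim probe sets, where 25 members were tested, 5 with the stricter filter, and from 0 to 10 when a donor was left out: 10 without A, 0 without B and 0 without C. Quantile normalization left CCL20 and NFKBIZ and lost IL6. The causes were not tested. Among the named genes, 295 values under the alternatives kept their direction and side of the threshold, 13 lost a call, 6 gained one and 5 changed sign with no call. Among the list medians these numbers were 287, 4, 14 and 27. Differences of dim genes, close to the level of the arrays' medians of 74.3 to 101, are limited by the signal over background, which the intensities do not give.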

Other observations

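The lists of ribosome biogenesis genes and of FOXO target genes were written after the pattern they address had been seen and before their own values were. The tests on exposure, scaling and exchanged arrays, and the genes named in this part, were chosen after the values had been seen.

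Some secreted factors outside the rule for named genes had large mean differences, though none passed over all genes. IL11, a cytokine of the IL-6 family, had 3.66 ± 2.28 (SD, n = 3), with 4.69 in donor A, 5.23 in B and 1.05 in C. HBEGF, a ligand of the EGF receptor, had 2.31 ± 1.42, BMP2 had 2.09 ± 1.15 and IL1B had 2.08 ± 1.43, and each was higher in all 3 donors. TNFSF10, the death ligand TRAIL, had −2.66 ± 1.94 and was lower in all 3. These genes were picked for their size and stand for no group: the fixed list of cytokines, which holds IL11, IL1B and TNFSF10, was not called (adjusted p = 0.134) and had medians of −0.06 in A, 0.25 in B and 0.29 in C, and IL6 and TSLP had their largest differences in C (1.52 and 1.16).

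Among the bright genes, 112 differed by over 2-fold in the same direction in donors A and B and by under 0.5 (log2) in donor C, where only 22 bright genes differed by over 2-fold at all; they comprised 60 higher genes, such as TXNIP (3.39 in A, 3.41 in B and 0.04 in C), and 52 lower ones, such as DDIT4 (−1.81, −2.37 and −0.02). The tables argue against the scaling between arrays, since 102 of the 112 genes still met these bounds after cyclic loess (averaging the probe sets of a gene gave 53 such genes). A weaker exposure of donor C was looked for in the IL-17 response list, whose median was 1.11 in C, 1.19 in B and −0.04 in A. On this list donor C responded about as much as B. The list did not move in A, so A gives no measure of exposure, and the question is not settled. A growth or nutrient stimulus in the treated cultures of A and B, such as fresh medium added with IL-17, is a candidate explanation that stays open, as does a true difference between donors in the response to IL-17, which was not tested. Ribosome biogenesis genes (20 tested) had medians of 0.22 in A, 0.45 in B and 0.06 in C. FOXO and growth-factor-withdrawal genes (21 tested) had −0.66, −0.36 and 0.03. Of these values in A and B, 3 lay outside the middle 95% of 10000 random lists of the same size and brightness. The ribosome median in A, at percentile 97.1, did not. Both lists were written with the pattern in view, and any genes they share with the 112 were left in. These percentiles are therefore no independent support for a growth or nutrient stimulus.

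The median of the IL-17 response list was near 0 in donor A and above 1 in donors B and C. An exchange of arrays within a pair is argued against by the differences across bright genes, whose correlation was 0.436 between donors A and B and above 0 for all pairs of donors, so that 0 pairs looked exchanged. An exchange would also leave a median near 0 where it is, since it only turns its sign. This covers that median alone, and medians further from 0 would turn. Of the 3 splits of the arrays that each turn round 1 pair, 1 gave a smaller camera p for the list than the real one (1.78e-12 against 6.78e-07), while the others gave 0.64 and 0.236. These genes may instead have been raised already in the untreated culture of donor A, but this stays open: their median level there was above donor B by 1.14 and above donor C by 0.072 (log2). With 1 pair of arrays per donor, a difference between donors and a difference between experiments cannot be told apart.

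The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. Of these, 4 part all 3 pairs, the real split among them. Among the 4, the real split gave 0 genes past the threshold and the highest of the others 0, and it gave 3 lists where the others gave 0, 2 and 8. The IL-17 response list had a camera p of 6.78e-07 in the real split and of 0.64, 0.236 and 1.78e-12 in the others, each of which turns round the arrays of 1 pair; the split with 8 lists is the one with the lowest p. The other 6 splits part 1 pair each, and with the donor block they come to 3 fits, each counted 2 times, that rest on the IL-17 and untreated arrays of 1 donor, so they are no regroupings by chance. With them included, 10 of the 10 splits gave as many genes, 8 as many lists and 6 as small a p for the IL-17 response list, numbers that carry no weight for or against chance.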
